A study of Mus musculus with 20 samples.

How the data were processed

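Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was carried out on cerebellum of CD1 mice at postnatal days 0, 5 and 15 (P0, P5, P15) and in adults (postnatal day 56, per the labels). At each of the 4 stages chromatin pooled from several cerebella was precipitated with antibodies against RNA polymerase II (RNAPII), histone H3 trimethylated at lysine 4 (H3K4me3, a mark of active promoters), histone H3 trimethylated at lysine 27 (H3K27me3, a mark of Polycomb-repressed chromatin) or with non-specific IgG as control. The labels give 1 library per antibody and stage, which makes 16 libraries, each assigned to its antibody and stage from its label. The 4 mRNA libraries of the series were not analysed here.

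The deposited alignment files list 1 aligned read per line as chromosome, start, end and strand, with end minus start of 35 in every line, and hold no counts, coverage or normalised signal. Reads were aligned to the mouse build mm9 with Bowtie, per the submitters' processing notes; the Bowtie version, its options and any filter on reads with several hits are not given in the sources used here. Repeated positions were kept in the deposited files, so that PCR duplicates and independent fragments are not separated there. The 8 deposited peak lists, for H3K4me3 and RNAPII at each stage, give the authors' peaks as single positions on a 5-base grid, with no width, height, score or p-value. The peak caller, its control and its threshold are not given in the sources used here. All coordinates are mm9, counted from 1.

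Everything else was computed from these positions. Each read was moved 75 bases towards the fragment centre and counted once. The annotation at hand belonged to a later mouse build and coordinates were not converted between builds, so no gene could be placed on these positions; gene lists, named genes and windows around annotated transcription start sites were replaced by positions in the authors' lists. H3K4me3 peaks of the 4 stages were chained where they lay within 2000 bases of each other, which gave 15765 regions with a median width of 2126 bases including a margin of 1000 bases on either side (2000 bases for H3K27me3). The planned count of RNAPII over gene bodies was replaced by 10-kb bins outside these regions with pooled RNAPII at least 2 times IgG. The planned comparison of alternative promoters of a gene was replaced by adjacent H3K4me3 regions at most 50 kb apart, which need not belong to the same gene. Peaks of different stages were matched within 500 bases, because positions without a width cannot overlap.

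The main test, fixed before the data were examined together with most alternatives, was a straight trend over the 4 ordered stages in limma (lmFit, eBayes with trend and robust) on log2(scaled reads + 1), two-sided, with Benjamini-Hochberg adjustment at 0.05 over all regions with at least 20 reads on average. The fitted change from P0 to adult is 3 times the slope and is on the log2(scaled reads + 1) scale, which understates changes from very low counts. With 1 library per stage there was no replicate check: departures from the straight line, with 2 residual degrees of freedom, stand in for the spread, and a region that changes in a single step scatters widely around the line. The eBayes step draws the variance of each region towards a value fitted over all regions. The SEs and p-values therefore rest in part on scatter pooled over regions of the same 4 libraries, and do not measure spread between animals or pools. Beside the trend, a fixed size rule took regions with at least a 2-fold ratio of scaled adult to scaled P0 reads, at least 40 reads in the higher library and a 95% exact conditional binomial interval that excluded 1. That rule compares these 2 libraries, not the stages, and its intervals cover counting error only, since reads without molecular identifiers are not independent molecules. Where a library had 0 reads, the fold was computed against a floor of 3 reads per library and is given as a lower bound, beside the lower limit of the exact interval, which is smaller. Shares carry exact Clopper-Pearson intervals at 95%. H3K4me3 and RNAPII were scaled by the median ratio to the mean library over regions with at least 20 reads in every stage, and H3K27me3 and IgG to RPM, reads per 1000000 aligned reads.

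Regions named in the text follow a rule: for each of H3K4me3, RNAPII and H3K27me3, the 10 higher and the 10 lower in adult with the largest fitted change among those past the trend test, filled up where fewer passed by regions of the 2-fold rule with P0 and P5 both on the same side of P15 and adult, and passing over regions within 50 kb of a region already taken. Neighbouring pairs were named by the largest change of share among those past the test. Other positions singled out were chosen after their values were seen. A region was said to carry H3K27me3 at a stage when it held at least 20 H3K27me3 reads and at least 3 times the IgG of that stage in RPM. H3K27me3 domains, defined after the data had been seen, were runs of 10-kb bins with at least 80 pooled H3K27me3 reads and pooled H3K27me3 at least 3 times IgG. As alternatives, also defined after the data had been seen, bins were chosen on P0 and P5 or on a single stage, with the read minimums scaled to the number of stages.

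The alternatives tried were the other scaling, removal of duplicates, a pseudocount of 5, a minimum of 50 reads or none, log2(postnatal day + 1) in place of stage order, windows of other widths, each stage left out in turn, thresholds of 1.5-fold and 3-fold, subtraction of IgG, other multiples of IgG, P5 against P15, and merging of peaks within 5 kb. Autosomes only, other distances, other stage pairs and a step between P5 and P15 in place of a straight trend were added after the data had been seen. Sequencing gave 5915637 to 11549150 aligned reads per library, and a median of 452.0 to 516.0 H3K4me3 reads, 17.0 to 23.0 RNAPII reads and 12.0 to 18.0 H3K27me3 reads per region and library, so that RNAPII ratios at single regions were far less precise than H3K4me3 ratios.

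The procedures were tested on simulated data, drawn for the real regions with known folds. For the trend test, every simulated change followed a straight course, with the same added scatter for every mark. In the real data the median residual SD (log2) was 0.2055 for H3K4me3, 0.2875 for RNAPII, 0.5483 for H3K27me3 and 0.3351 for neighbouring pairs. The recovered shares therefore do not hold for stepped changes or for scatter larger than simulated. Of regions changed 4-fold along the trend, the test recovered 100% of 67 for H3K4me3 (14937 regions), 67.2% of 67 for RNAPII (8106 regions), 92.5% of 67 for H3K27me3 (6341 regions) and 92.5% of 67 neighbouring pairs (6783 pairs). At 2-fold it recovered 29.9%, 7.46%, 32.8% and 11.9%, in the same order. The 2-fold rule, over 15765 regions, called all regions with a simulated 4-fold change and at least 40 reads. It called 0.022%, 0.839% and 0.189% of regions with equal H3K4me3, RNAPII and H3K27me3 levels. Of regions simulated at 2-fold, it called 39.1% of 46, 52.6% of 19 and 53.85% of 13, in the same order. These reads were drawn with counting error alone, so the shares at equal levels are not rates of false calls between 2 real libraries. Among real IgG regions with at least 40 reads, the rule called 4 of 27. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9, R 4.3.3 and limma 3.58.1 were used.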

Results

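Chromatin of mouse cerebellum was profiled at 4 stages that span its postnatal development, from P0 and P5 through P15 to the adult. For each stage there was 1 library of H3K4me3, RNAPII, H3K27me3 and IgG. The series asks how transcription, as opposed to splicing, contributes to the diversity of transcripts in the developing cerebellum. Aligned reads per library numbered 10472017 to 11549150 for H3K4me3, 8570495 to 10269224 for RNAPII, 6582334 to 11342030 for H3K27me3 and 5915637 to 10913406 for IgG. The 15765 H3K4me3 regions, 1.57% of the genome, held 78.3% of H3K4me3 reads at P0, 89.7% at P5, 91.3% at P15 and 93.1% in the adult. They held 3.14% to 4.89% of RNAPII reads, 4.86% to 10.9% of H3K27me3 reads and 1.73% to 2.19% of IgG reads. Of these regions, 12690 had a deposited H3K4me3 peak in all 4 stages and 1018 in a single stage. With 1 library per antibody and stage there was no replicate check, a comparison of 2 libraries is not one of 2 stages, and the intervals given cover counting error only.

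H3K4me3 was redistributed over a large share of regions between birth and adulthood, and lower levels in the adult were more frequent than higher ones. Of 14375 regions with enough reads, 1335 were at least 2-fold higher in the adult library than in the P0 library and 2688 were at least 2-fold lower. In RPM in place of the median ratio, 1824 were higher and 2444 lower. Most of the difference lay between P5 and P15 and between P15 and adult: 707 regions passed the same rule between P0 and P5 (68 higher and 639 lower at P5), 2355 between P5 and P15 (1430 higher and 925 lower at P15), and 2205 between P15 and adult (493 higher and 1712 lower in the adult). In 90.9% (95% CI 89.3 to 92.4%) of the 1335 regions that were higher in the adult, P15 and adult both lay above P0 and P5. The corresponding share of the 2688 lower regions was 75.6% (95% CI 74.0 to 77.2%). A part of this order follows from choosing the regions on P0 and adult. Across regions, H3K4me3 had a rank correlation of 0.985 between P0 and P5 and of 0.859 between P0 and adult.

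Single regions changed far more than 2-fold. On chromosome 11, the region with peaks from 42131075 to 42134265 held 2, 13, 634 and 622 H3K4me3 reads at P0, P5, P15 and adult, a ratio of adult to P0 of 291 (95% CI 80.2 to 2407). On chromosome 7, the region from 90879530 to 90883595 went from 10 to 1469 reads, a ratio of 137 (74.5 to 287), and the region from 133392315 to 133395765 from 29 to 2170 reads, a ratio of 70.0 (48.6 to 105). At chromosome 1, 178684280 to 178685530, there were 0 reads at P0 and 132 in the adult, at least 41.1-fold higher against a floor of 3 reads, with a lower 95% limit of 33.0. In the other direction, the region on chromosome 11 from 95866190 to 95868720 held 1114, 219, 3 and 1 reads, 1191-fold lower in the adult (95% CI 213 to 47090). The region on chromosome 16 from 22161840 to 22163465 stepped down through 1974, 880, 147 and 21 reads, 100.5-fold (65.6 to 163) from P0 to adult. On chromosome 10, the region from 119911620 to 119914755 went from 1055 to 3 reads, 376-fold lower (128 to 1826). At chromosome 15, 85036540, 98 reads at P0 stood against 0 in the adult, at least 34.9-fold lower against the same floor, with a lower 95% limit of 27.9.

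**Figure D1:**
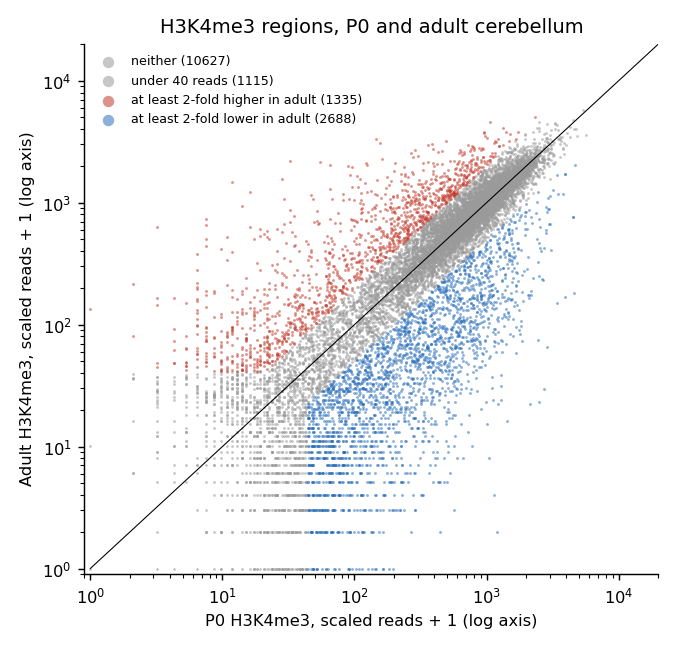
Scaled H3K4me3 reads plus 1 in each of the 15765 regions at P0 (horizontal, log axis) and in the adult (vertical, log axis), 1 library per stage; the line marks equal levels. The 1335 regions at least 2-fold higher in the adult are red, the 2688 at least 2-fold lower are blue, and the rest are grey.

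As a trend over stage order, 0 of 14937 regions passed limma's test after Benjamini-Hochberg adjustment, although 4236 had an unadjusted p under 0.05, where 747 are expected by chance. The smallest adjusted p was 0.0559, and the named regions above are therefore described by the 2-fold rule alone. RPM (reads per 1000000 aligned reads) in place of the median ratio moved the median fitted change from -0.04 to 0.18 on the log2 scale and gave 471 calls. Leaving out P0, P5, P15 or adult gave 957, 0, 1916 and 279 calls.

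H3K27me3 was mostly higher in the adult over those of the same regions that held enough of its reads. Relative to all aligned reads, 3195 of 5150 regions with enough reads were at least 2-fold higher in the adult than at P0 and 613 were at least 2-fold lower. The minimum of 40 reads in the higher library was not scaled to library size. The adult library held 11342030 aligned reads and the P0 library 7746529. Regions high in the adult therefore passed this minimum at a lower RPM than regions high at P0, which favours the higher group. The effect of this minimum on the 2-fold split was not tested. The trend test (limma, adjusted p under 0.05) found 1116 rising and 208 falling regions among 6341. On chromosome 13, H3K27me3 over the region from 23665760 to 23668535 rose through 3, 13, 53 and 1231 reads, a fitted change of 7.36 ± 0.97 (log2, SE; adjusted p = 2.92e-08). On chromosome 3, the region from 55046680 to 55047620 rose from 12 to 1090 reads, with a fitted change of 6.02 ± 0.91 (adjusted p = 4.07e-07). On chromosome 12, the region from 28023160 to 28028390 rose from 20 to 1354 reads, with a fitted change of 5.71 ± 0.85. Among falling regions, the one on chromosome 18 from 36446175 to 36447225 went from 113 reads to 1, a fitted change of -6.75 ± 0.99 (adjusted p = 4.07e-07), and the one on chromosome 8 from 87500255 to 87502380 went from 150 to 13 reads, a fitted change of -4.61 ± 0.99.

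The size and balance of these H3K27me3 counts depended on the scaling, the window and the filter and, for regions lower by the 2-fold rule, on duplicates. The median ratio over regions, which sets the typical marked region equal between stages, moved the median fitted change from 0.83 to -0.12, changed the 2-fold split from 83.9% to 57.6% higher (1559 higher, 1146 lower) and left 0 trend calls in limma, with 1948 regions at an unadjusted p under 0.05. With duplicates removed, 2855 regions were at least 2-fold higher and 237 at least 2-fold lower. A window of 2 times the width, with 11859 regions tested, gave 1003 rising and 799 falling regions and a median fitted change of -0.34, and no filter on reads gave 1058 and 751, with a median of -0.49 over 15752 regions. A step between P5 and P15 in place of the straight trend gave 78 calls, and leaving out P5, P15 or adult gave 409, 821 and 39. The P0 library held 57.8% duplicate reads, against 15.8% to 33.2% at the later stages. Relative to IgG, the median autosomal 10-kb bin went from 0.866 at P0 to 0.454 in the adult, so that a fall in RPM of about that size also occurred outside marked regions.

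Where H3K4me3 was lower in the adult, H3K27me3 was higher in sum and in most regions with enough of its reads. Over the 2588 autosomal regions with at least 2-fold less H3K4me3, summed H3K27me3 RPM was 3.72-fold (95% CI 3.70 to 3.74) that at P0, and RNAPII was 0.622-fold (0.614 to 0.629) by the median ratio. Of the 2247 of these regions with at least 20 H3K27me3 reads on average, a minimum that high adult reads alone can meet, 95.6% had more H3K27me3 RPM in the adult. Of the 2588 regions, 621 did not carry H3K27me3 in the adult by the rule of 20 reads and 3 times IgG. Over the 1313 autosomal regions with at least 2-fold more H3K4me3, H3K27me3 was 0.741-fold (0.734 to 0.749) and RNAPII 1.19-fold (1.18 to 1.21). The 10227 autosomal regions with neither change and at least 40 H3K4me3 reads in at least 1 stage had ratios of 1.03 for H3K27me3 and 0.981 for RNAPII. IgG differed little in any of the 3 groups, with ratios of 1.002, 1.09 and 1.04. With H3K27me3 scaled by the median ratio, the 3 H3K27me3 ratios became 1.70, 0.339 and 0.470, and with RNAPII in RPM, its ratios became 0.816, 1.56 and 1.29.

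**Figure D2:**
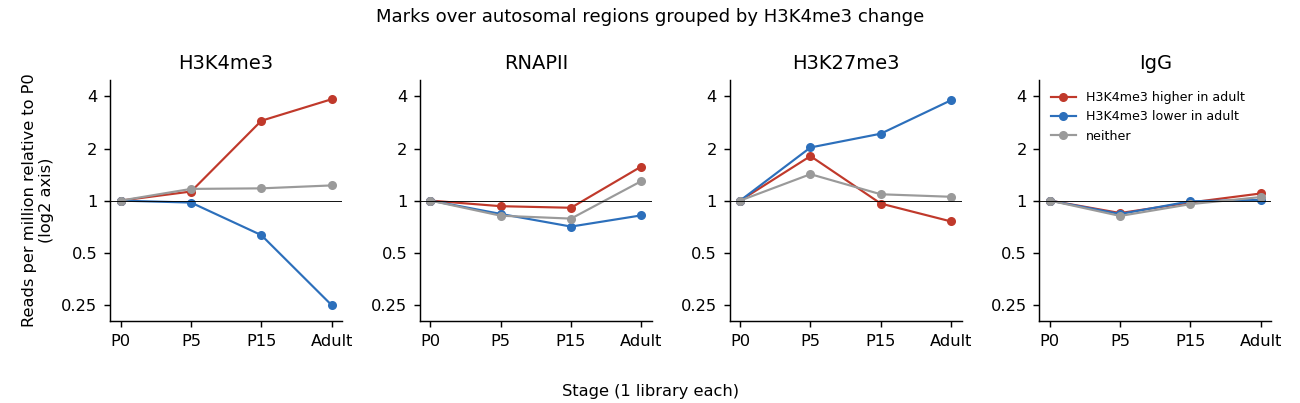
RPM over autosomal reads, relative to P0 (log2 axis) at each stage, summed over autosomal regions with at least 2-fold higher H3K4me3 in the adult (red, 1313 regions), at least 2-fold lower (blue, 2588) or neither (grey, 10227), 1 library per point. The grey group is limited to regions with at least 40 H3K4me3 reads in at least 1 stage. In the adult, H3K27me3 was 3.81-fold its P0 level in the blue group and 0.758-fold in the red group, while the IgG ratio was at most 1.13 at its upper 95% limit.

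The same opposition held from the side of H3K27me3. Of 1027 autosomal regions with rising H3K27me3 that were also tested for H3K4me3, 998 (97.2%) had a negative fitted H3K4me3 change, with a median of -2.63, against 54.3% of 4351 regions with no call. RNAPII had a negative fitted change in 331 of 352 such regions (94.0%), against 62.6% of 2189 with no call. Of 205 autosomal regions with falling H3K27me3, 172 had a positive fitted H3K4me3 change, and 98 of 158 had a positive fitted RNAPII change. All 10 named regions with the largest H3K27me3 rise had lower H3K4me3 in the adult: on chromosome 13, the region from 60277605 to 60279815 went from 20 to 1125 H3K27me3 reads and from 2419 to 233 H3K4me3 reads. Of the 10 named regions with the largest H3K27me3 fall, 9 had higher H3K4me3 by the median ratio and all 10 in RPM, such as the region on chromosome 8 from 87500255 to 87502380 with 229 and 995 H3K4me3 reads.

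Regions that already carried H3K27me3 at P0 had lower H3K4me3 in the adult more often than the rest. Both groupings given here are limited to autosomal regions with at least 40 H3K4me3 reads in at least 1 stage. At least 2-fold lower H3K4me3 in the adult was seen in 975 of 2045 such regions with H3K27me3 at P0 (47.7%, 95% CI 45.5 to 49.9%) and in 13.3% (12.7 to 14.0%) of 12083 without it. Higher H3K4me3 was seen in 15.8% and 8.19% of the same groups. Grouped by H3K27me3 in the adult, the share with lower H3K4me3 was 66.0% (64.3 to 67.7%) of 2980 regions with the mark and 5.57% (5.15 to 6.01%) of 11148 without it.

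Across the 15144 autosomal regions, H3K4me3 and RNAPII were more closely correlated in the adult than at P0, and both had lower correlations with H3K27me3. The rank correlation of H3K4me3 with RNAPII was 0.552 (95% bootstrap CI 0.540 to 0.565) at P0, 0.482 at P5, 0.535 at P15 and 0.684 (0.675 to 0.694) in the adult. That of H3K4me3 with H3K27me3 went from -0.165 (-0.181 to -0.151) at P0 through -0.247 at P5 and -0.271 at P15 to -0.460 (-0.472 to -0.447) in the adult. RNAPII and H3K27me3 had a correlation of 0.130 at P0 and of -0.271 in the adult, and of 0.052 and -0.369 with IgG subtracted. Reads were not divided by the width of the region, and wide regions can hold more reads of every antibody. The change in H3K4me3 from P0 to adult had a rank correlation of 0.376 with the change in RNAPII and of -0.431 with the change in H3K27me3, compared with 0.05 for the change in IgG. These are correlations across regions within pairs of libraries, 16 in all, and regions are not independent replicates. Poor enrichment of a library also weakens such correlations, and enrichment differed between stages. H3K27me3 domains held 12.9%, 25.8%, 28.5% and 35.6% of autosomal H3K27me3 reads at P0, P5, P15 and adult. The regions held 4.0%, 3.34%, 3.14% and 4.89% of RNAPII reads. A change with stage was not separated from these differences between libraries.

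Both H3K4me3 and H3K27me3 marked a sizeable minority of regions at every stage. Of regions with an H3K4me3 peak, 14.3% (95% CI 13.7 to 14.9%) also carried H3K27me3 at P0, 21.0% (20.3 to 21.7%) at P5, 16.03% (15.4 to 16.6%) at P15 and 15.8% (15.2 to 16.4%) in the adult. By this rule, membership differed between the libraries: of 2078 regions with both marks at P0, 991 had both in the adult and 864 had both at all 4 stages. Another 617 had lost the H3K4me3 peak and kept H3K27me3 by adulthood, and 449 had kept the H3K4me3 peak without H3K27me3. In the adult, 1032 regions had both marks that at P0 had an H3K4me3 peak alone. The share at P0 was 22.0% with a threshold of 2 times IgG and 8.35% with 5 times, so the level depends on that threshold. Membership is a threshold call on libraries that differ in depth, duplicates and enrichment, so gains and losses may be differences in detection. In chromatin from whole tissue, both marks at a region need not lie in the same cells.

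RNAPII changed less, or less measurably, than the histone marks. Of 3425 regions with enough reads, 211 were at least 2-fold higher in the adult and 254 at least 2-fold lower. For IgG the same rule called 4 of 27 regions, a share no lower than that for RNAPII, though from few regions. The RNAPII count is therefore not shown to exceed that of the control. The trend test called 4 of 8106 regions, all of them falling. On chromosome 2, RNAPII over the region from 146047225 to 146051325 fell through 165, 156, 46 and 48 reads, a fitted change of -2.19 ± 0.38 (limma, adjusted p = 0.00552), while H3K4me3 there went from 1753 to 152 reads and H3K27me3 from 235 to 1721. On chromosome 13, the region from 34220735 to 34225575 fell from 139 to 39 reads (fitted change -1.88 ± 0.36, adjusted p = 0.0130), with H3K4me3 going from 1674 to 104 reads. The region on chromosome 1 from 19199970 to 19204970 fell from 136 to 31 reads (-2.16 ± 0.36, adjusted p = 0.00477) and that on chromosome 7 from 86680640 to 86681155 from 57 to 13 (-2.21 ± 0.45, adjusted p = 0.0342). Among regions with higher RNAPII in the adult, that on chromosome 14 from 70857560 to 70861570 went from 37 to 128 RNAPII reads, 3.16-fold (95% CI 2.18 to 4.69), and from 144 to 3055 H3K4me3 reads. H3K4me3 RPM was higher in the adult in 9 of the 10 named regions with higher RNAPII and lower in 9 of the 10 with lower RNAPII.

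RNAPII counts were small and moved with the settings. In RPM, the 2-fold split turned from 45.4% higher to 87.0% higher (682 higher, 102 lower), the median fitted change went from -0.04 to 0.30, and the trend test in limma called 0 regions, with 243 at an unadjusted p under 0.05. Leaving out P0, P5, P15 or adult gave 14, 0, 60 and 14 calls. In 10-kb bins outside the H3K4me3 regions, 5 of 362 were called, 4 of them rising, such as chromosome 17 from 27590001 to 27600000 with 72, 82, 106 and 225 reads (fitted change 2.03 ± 0.53, limma adjusted p = 0.0121). The falling bin was on chromosome 12 from 34640001 to 34650000, with 186 reads at P0 and 26 in the adult (-2.06 ± 0.52, adjusted p = 0.0114). In RPM, 0 bins passed in limma (21 at an unadjusted p under 0.05), and leaving out P0, P5, P15 or adult gave 12, 128, 0 and 0.

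IgG, counted over the same regions, gave 0 trend calls among 656 regions in limma, with 29 at an unadjusted p under 0.05 and 33 expected by chance, and 16 and 2 calls without P0 and without adult. By the 2-fold rule, 4 of 27 IgG regions with enough reads differed between P0 and adult.

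The use of alternative promoters was approached through H3K4me3 regions that lie next to each other within 50 kb. The balance of H3K4me3 within such pairs shifted with stage in 179 of 6783 pairs (limma, adjusted p under 0.05), 79 towards the left and 100 towards the right member in genome coordinates. The largest change was on chromosome 11, where the left member of the pair at 95866190 and 95896450 went from 76.3% (95% CI 74.0 to 78.5%) to 0.245% (0.00619 to 1.36%) of the pair's H3K4me3 reads (fitted change -10.2 ± 1.28, adjusted p = 0.0495), while its share of RNAPII reads was 77.7% (67.9 to 85.6%) and 81.5% (70.0 to 90.1%). The right member changed little, with 346, 342, 389 and 408 H3K4me3 reads, and the left fell from 1114 to 1. A shifted share can thus reflect a change in 1 member alone, without a gain in the other. On chromosome 2, the pair at 35477700 and 35517220, the last of the 10 named, exchanged places: the left member held 14.1% (95% CI 12.4 to 15.97%) of the pair's reads at P0, 32.4% at P5, 80.3% at P15 and 92.8% (91.4 to 94.1%) in the adult. Its share of RNAPII reads went from 37.7% (26.9 to 49.4%) to 64.0% (54.5 to 72.8%). On chromosome 11, the pair at 94352605 and 94359995, whose facing peaks are 7350 bases apart, shifted from 70.6% (59.7 to 79.98%) to 0.88% (0.286 to 2.04%) on the left. On chromosome 8, the share of the left member of the pair at 12948085 and 12984990 went from 98.6% (97.0 to 99.5%) to 23.2% (20.03 to 26.7%), and on chromosome 4 that at 154771955 and 154783485 went from 10.6% (7.004 to 15.3%) to 93.0% (91.7 to 94.2%). Over the 10 named pairs, the intervals of the RNAPII share at P0 and adult overlapped in 7, and in the other 3 the share moved with that of H3K4me3. Those 3 include both named pairs that contain the region on chromosome 7 from 133392315 to 133395765, so they are not 3 separate cases.

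Neighbouring regions more often changed the same way than partners drawn at random. In 2157 pairs only 1 member passed the 2-fold rule, in 343 both changed the same way, and in 122 they changed in opposite directions. When partners were shuffled 1000 times, opposite pairs numbered 175 on average (140 to 214) and pairs changing the same way 176 (at most 216). Among the 77 called pairs with enough RNAPII reads, the RNAPII share moved the same way as the H3K4me3 share in 66 (85.7%), compared with 58.2% of all 2279 pairs tested for both. On RNAPII alone, 1 of 2279 pairs was called. The 179 calls lay close to the threshold: removing duplicates, requiring 50 reads or merging peaks within 5 kb left 0 in limma (2020, 1584 and 1876 at an unadjusted p under 0.05), and leaving out P0, P5, P15 or adult gave 828, 540, 0 and 18.

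Most of the authors' H3K4me3 peak positions at P0 had a counterpart at P5 and in the adult. Within 500 bases, 91.6% (95% CI 91.2 to 91.9%) of P0 H3K4me3 peaks had a P5 peak and 83.0% (82.5 to 83.5%) an adult peak, and 94.0% of adult peaks had a P15 peak. For RNAPII, 25.7% (25.3 to 26.1%) of adult peaks had a P0 peak and 6.93% (6.81 to 7.06%) of P0 peaks had an adult peak. The P0 RNAPII list is unlike the others: 128426 of its 159641 positions (80.4%) are on chromosome 14, compared with 4.32% to 5.54% at the later stages. Without chromosome 14, 25.7% of P0 RNAPII peaks had an adult peak and 21.5% of adult peaks a P0 peak. On the other autosomes, RNAPII peaks lay within 1 kb of an H3K4me3 peak in 27.1% of cases at P0, 13.1% at P5, 8.85% at P15 and 30.95% in the adult; on chromosome 14 at P0 it was 1.40%. Lists without a stated threshold differ in length for reasons other than binding, so their lengths are not compared, and the RNAPII shares above depend on these lengths and thresholds too.

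**Figure D3:**
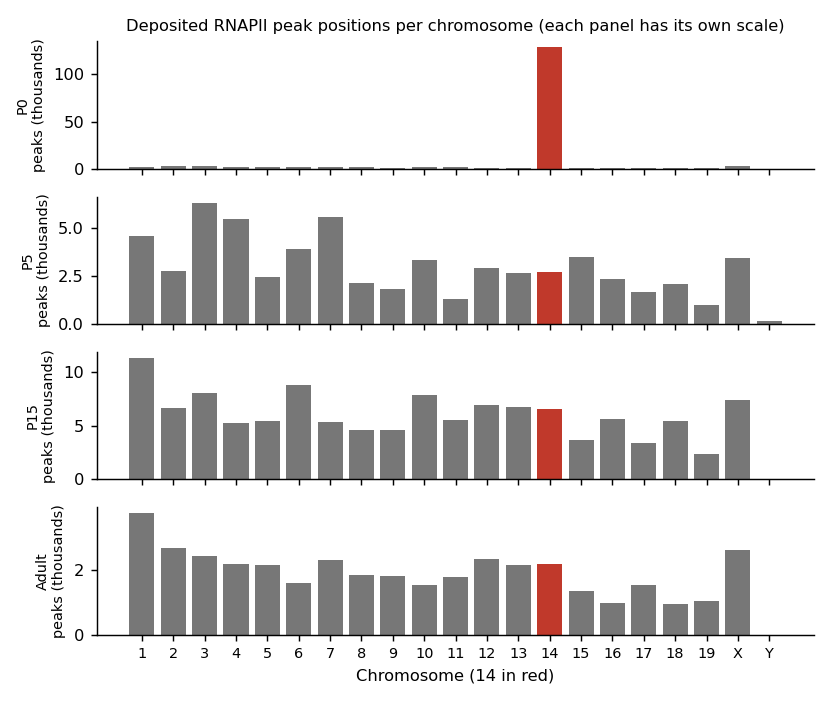
Number of deposited RNAPII peak positions (in units of 1000, each stage on its own axis) per chromosome, with chromosome 14 in red. At P0 chromosome 14 holds 128426 of 159641 positions, and at the later stages it does not stand out.

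Outside single regions, H3K27me3 lay in domains that held a larger share of its reads in the libraries of later stages than in the P0 library. The 3530 autosomal domains, 64.7 Mb in all and 244 of them at least 50 kb long, held 12.9% of autosomal H3K27me3 reads at P0, 25.8% at P5, 28.5% at P15 and 35.6% in the adult, with 3.12% to 3.47% of IgG reads. These domains were chosen on reads pooled over the stages, which favours bins that are high in the larger libraries. The P0 library, with 57.8% duplicates, held 3269996 distinct positions, compared with 4604157 to 9170568 at the later stages; with duplicates removed, the shares were 14.58%, 26.96%, 28.9% and 36.69%. In bins chosen on P0 alone the share was 9.71% at P0, 19.8% at P5, 16.5% at P15 and 18.3% in the adult, so that in those bins the rise from P0 to P5 remained and a further rise after P5 did not. The strongest of at least 50 kb were on chromosome 6 from 52090001 to 52280000 (14.0 times IgG at P0, 53.7 at P5, 33.0 at P15 and 22.5 in the adult), on chromosome 15 from 102720001 to 103020000, on chromosome 11 from 95980001 to 96270000 and on chromosome 2 from 74480001 to 74610000. All 4 were highest at P5 relative to IgG. Among 649 long and well-covered domains, 90 gained and 109 lost at least 2-fold from P0 to adult relative to the median domain. The largest relative loss was on chromosome 2 from 105500001 to 105530000, which stood at 60.7, 108, 14.2 and 10.1 times IgG at P0, P5, P15 and adult. The largest relative gain was on chromosome 5 from 143710001 to 143740000, which stood at 0.845, 2.36, 16.5 and 23.0 times IgG.

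**Figure D4:**
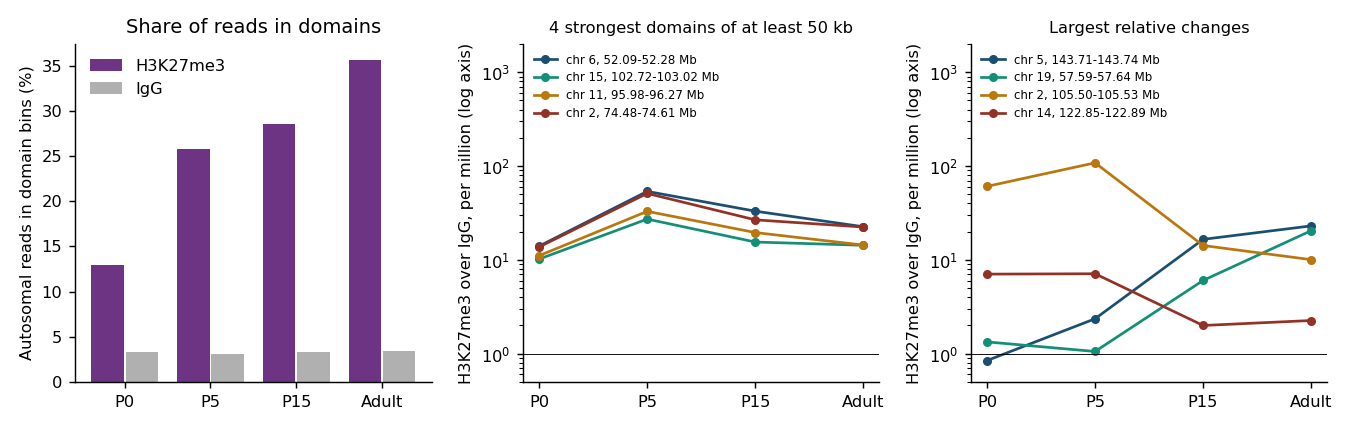
Left, percent of autosomal reads inside H3K27me3 domains at each stage for H3K27me3 and IgG; middle and right, H3K27me3 over IgG in RPM (log axis) for the 4 strongest domains of at least 50 kb and for the domains with the largest change relative to the median domain, 1 library per antibody and stage. In these domains, chosen on reads pooled over stages, the share rose from 12.9% to 35.6% for H3K27me3 and stayed between 3.12% and 3.47% for IgG.

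The share of reads on the sex chromosomes differed between libraries of the same tissue. H3K27me3 reads on chromosome X made up 3.40% at P0, 4.91% at P5, 1.85% at P15 and 5.56% in the adult, with counting intervals no wider than 4.89 to 4.92%. Reads on chromosome Y numbered 648, 235, 722 and 55.2 RPM in the same libraries. In the adult, Y reads were also low for RNAPII (46.3 RPM, 550 to 766 RPM earlier), IgG (198, compared with 600 to 819) and H3K4me3 (5.54, compared with 62.2 to 197). The X share in the adult was 3.87% for RNAPII, 4.18% for IgG and 1.94% for H3K4me3. Of the 1116 regions with rising H3K27me3, 15 are on X, and with autosomes alone 1491 regions were called in the trend test. By the 2-fold rule, 2934 of the 3195 regions with higher H3K27me3 are on autosomes.

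**Figure D5:**
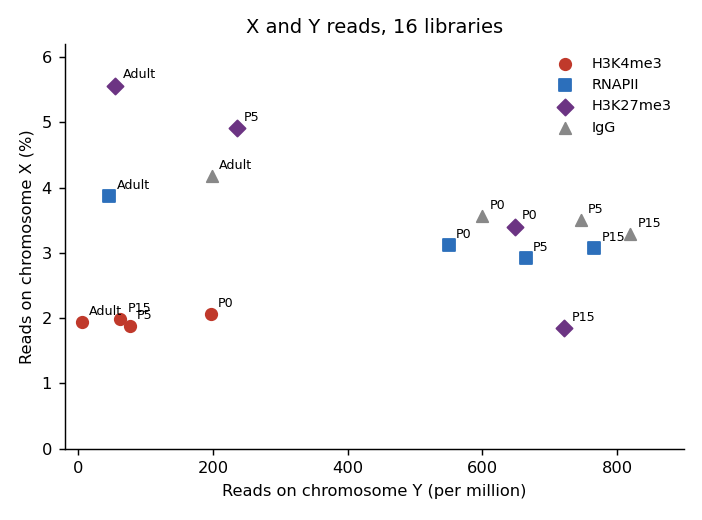
Percent of reads on chromosome X against RPM on chromosome Y for the 16 libraries, labelled by stage, with the symbol giving the antibody. The adult libraries lie at the left of their antibody, between 5.54 and 198 RPM on Y, and H3K27me3 spans 1.85% to 5.56% on X.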

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

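All tests in this part were chosen after the results they address had been seen.

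Among 22 sets of 4 libraries compared on duplicates, sex chromosomes, reads in H3K4me3 regions, domains and peak lists, a P0 peak list lay far from the other stages in 2, and chance alone gives such a gap in about 1 set in 20. The share of P0 RNAPII peaks on chromosome 14 was 80.4%, with 4.32% to 5.54% at the other stages. The share of P0 H3K4me3 peaks on chromosome 14 was 3.68%, with 3.78% to 3.79% at the other stages, a difference of about 0.1 percentage points.

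The excess of P0 RNAPII positions on chromosome 14 was set against binding, reads and threshold. RNAPII over IgG at these positions was 0.43 times that at P0 positions on the other autosomes, which argues against stronger binding there. Chromosome 14 held 4.37% of P0 RNAPII reads and 4.47% of P0 IgG reads, a ratio of 0.978, which argues against extra reads. The median position on chromosome 14 had 3 reads within 250 bases and the median position on other autosomes had 11, a ratio of 0.273, so a lower threshold for that chromosome in the deposited list is a candidate explanation. No other biological explanation was tested.

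The higher H3K27me3 in the adult where H3K4me3 was lower was set against the quality of the P0 H3K27me3 library. Autosomal regions with H3K27me3 in at least 1 stage and at least 40 H3K4me3 reads at P0 or adult were compared. The median log2 ratio of adult to P0 was 2.21 (95% CI 2.17 to 2.27) where H3K4me3 was lower. It was 0.33 (0.19 to 0.45) where H3K4me3 had neither change, a difference of 1.89. A poorly enriched P0 library could raise strongly marked regions more than weakly marked ones. The groups were not matched on H3K27me3 level, so this comparison cannot decide on enrichment. With duplicates removed the summed ratio was 3.35 (3.33 to 3.37), and adult over P5, without the P0 library, it was 1.88 (1.87 to 1.88). Duplicates or the P0 library alone do not account for the whole pattern. The ratio from P5 is smaller than that from P0, so that a part of the size may come from the P0 library. Unequal enrichment of the libraries stays open. A difference between the stages themselves, including a change in the makeup of cell types in a tissue that grows between P0 and P15, stays open and was not tested.

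The X share of H3K27me3 reads was 3.00 times higher in the adult than at P15, more than a difference in the number of X copies can give with equal marking of every copy, and 3.06 times with duplicates removed. In 6 of 6 pairs of the H3K27me3 libraries, more X reads went with fewer Y reads, as pools of different sex composition with more H3K27me3 on an inactive X would give. The same held in 6 of 6 pairs for IgG, 5 of 6 for RNAPII and 2 of 6 for H3K4me3. From P0 to adult, Y reads fell for every antibody, but from P0 to P5 they went to 0.363 times for H3K27me3 and 0.391 times for H3K4me3, and to 1.21 and 1.24 times for RNAPII and IgG, so the P5 step is not shared by all P5 libraries. The sex of the animals, and whether the libraries of a stage came from the same pool, are not given in the labels used here. Sex composition therefore stays open, and a difference between stages in H3K27me3 on X stays open as well. Of 11379 X bins with enough reads, 93.0% were higher in the adult than at P15, so the difference extended over the chromosome.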

How the results depend on the processing

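Autosomes only, a step between P5 and P15, all stage pairs other than P0 against adult and P5 against P15, other neighbour and matching distances, lists without chromosome 14, the alternatives for H3K27me3 domains and the count of both marks without a read minimum were added after the data had been seen; all other alternatives were planned. Counts that changed by more than 1.5 times in total are given here, and some counts are also given by direction, and the cause was not tested unless stated.

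H3K4me3 trend calls, 0 in the main setting, numbered 471 in RPM, 910 with a step between P5 and P15, and 0 to 1916 with a stage left out (0 without P5, 1916 without P15). They stayed at 0 without duplicates, with pseudocount 5, with a minimum of 50 reads or none, with log2(postnatal day + 1) and with either other window. RNAPII trend calls, 4 in the main setting, numbered 0 in RPM, 27 without duplicates, 10 with a minimum of 50 reads, 22 with log2(postnatal day + 1), 53 and 22 with windows of smaller and larger width, 1 with the step, and 0 to 60 with a stage left out. H3K27me3 trend calls, 1324 in the main setting, numbered 0 with the median ratio, 757 with log2(postnatal day + 1), 78 with the step, and 39 to 1024 with a stage left out; 1153 of the calls were shared with the 1326 made without duplicates. The split of 1116 rising and 208 falling became 1003 and 799 with the wider window, 1058 and 751 with no filter, 726 and 31 with log2(postnatal day + 1) and 651 and 373 without P0, and the median fitted change, 0.83 in the main setting, was -0.34 with the wider window and -0.49 with no filter. Leaving out a stage leaves 1 residual degree of freedom. IgG gave 0 to 16 calls with a stage left out and 0 otherwise. RNAPII bins, 5 in the main setting, gave 0 in RPM, 9 with log2(postnatal day + 1), 0 with the step and 0 to 128 with a stage left out.

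Neighbouring pairs with a shifted H3K4me3 share, 179 in the main setting, numbered 0 with peaks merged within 5 kb, 0 without duplicates, 0 with 50 reads and 0 to 828 with a stage left out, and with pseudocount 5 there were 263 and within 20 kb 180. For RNAPII shares, the single call became 2 without duplicates, 3 with pseudocount 5, 0 with 50 reads, where 19 pairs were left to test, 0 within 20 kb and 0 to 5 with a stage left out. No paired analysis was possible because each stage has 1 library per antibody.

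The 2-fold count for H3K4me3 stayed between 2835 and 5710 under all alternatives on P0 and adult, and was 2355 for P5 against P15, 707 for P0 against P5, 2444 for P0 against P15 and 2205 for P15 against adult, all shorter intervals. That for RNAPII, 465, became 784 in RPM, 1111 at 1.5-fold, 90 at 3-fold, 924 with IgG subtracted, 102 for P5 against P15, 158 for P0 against P5, 282 for P0 against P15 and 268 for P15 against adult. That for H3K27me3, 3808, became 1467 for P5 against P15, 1926 for P0 against P5, 2197 for P0 against P15, 2498 for P15 against adult and 3114 for P5 against adult. Its split of 3195 higher and 613 lower became 1559 and 1146 with the median ratio, 2855 and 237 without duplicates, 625 and 842 for P5 against P15 and 2154 and 960 for P5 against adult. The split for H3K4me3, 1335 higher and 2688 lower, became 1824 and 2444 in RPM, 2357 and 3353 at 1.5-fold, 734 and 2101 at 3-fold and 1430 and 925 for P5 against P15. The 4 IgG regions became 9 at 1.5-fold, 1 at 3-fold, 14 for P5 against P15, and 9 each for P0 against P15 and P15 against adult.

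The share of H3K4me3 regions that also carried H3K27me3 at P0, P5, P15 and adult was 22.0%, 26.7%, 20.9% and 19.8% at 2 times IgG and 8.35%, 14.8%, 11.99% and 12.3% at 5 times IgG; P5 was highest at each threshold. Without duplicates it was 13.6% at P0. The correlation of H3K4me3 with RNAPII was 0.582 at P0 and 0.701 in the adult without duplicates, and 0.484 and 0.647 with IgG subtracted. That of H3K4me3 with H3K27me3 was -0.129 and -0.443 without duplicates, and -0.247 and -0.545 with IgG subtracted. The correlations of changes with IgG subtracted were 0.306 for RNAPII and -0.449 for H3K27me3. None of these changed sign. The correlation of RNAPII with H3K27me3 at P15 did, from 0.042 in the main setting to -0.072 with IgG subtracted.

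Peak matching within 250 and 1000 bases gave 87.9% and 95.5% for H3K4me3 at P0 near P5, 79.3% and 87.2% at P0 near adult, and 90.9% and 97.1% in the adult near P15. For RNAPII it gave 4.99% and 9.53% at P0 near adult and 19.9% and 30.4% in the adult near P0. Without chromosome 14 those RNAPII shares were 25.7% and 21.5%.

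The share of H3K27me3 reads in domains at P0, P5, P15 and adult, 12.9%, 25.8%, 28.5% and 35.6% in the main setting, was 9.71%, 19.8%, 16.5% and 18.3% with bins chosen on P0 alone, 10.8%, 22.8%, 20.1% and 22.4% with P0 and P5, and 14.5%, 27.1%, 31.5% and 42.8% with adult alone. It was higher at P5 than at P0 in every setting, and its course after P5 depended on the stages used to choose the bins.

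Of 262 values of the 20 named H3K27me3 regions under the alternatives, 210 kept direction and side of the threshold, 51 lost the call and 1 reversed: on chromosome 1, the region from 193220140 to 193221390 had a fitted change of 0.11 without adult and of -7.96 without P0, so that its fall rests on the adult library. For the 20 named H3K4me3 regions, 216 of 276 values stayed and 60 gained a call, and for the 20 RNAPII regions 199 of 248 stayed, 18 lost and 31 gained a call. Gene list trends, overlap by part of the peak and the upper part of each list by score were not run, because no genes could be placed and the peaks have no width or score. In simulated data the trend test recovered the lowest share of changes for RNAPII, 7.46% of 2-fold and 67.2% of 4-fold changes. The simulation used the same scatter, folds and straight courses for every mark. The difference between marks therefore reflects read numbers and the number of regions tested, which were not separated.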

Other observations

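The count of regions with an extreme at a middle stage and the domains named here were chosen after the data had been seen.

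A small set of regions had its highest H3K4me3 between birth and adulthood. In 135 regions the level at P5 or P15 was at least 2-fold above both P0 and adult, with the maximum at P5 in 27 and at P15 in 108. On chromosome 11, the regions at 21896825 and from 21901125 to 21902875 shared this course, with 14.1, 62.6, 146 and 3.0 scaled reads in the former and 104, 531, 626 and 31.4 in the latter at P0, P5, P15 and adult. On chromosome 4, the region from 81216825 to 81219150 peaked at P5, with 22.8, 215, 58.6 and 4.1 scaled reads. On chromosome 2, the region from 154382950 to 154384390 peaked at P15 with 1218 scaled reads, compared with 125 at P0 and 224 in the adult. The opposite course, at least 2-fold below both ends at P5 or P15, was seen in 266 regions. With 1 library per stage, a single library that deviates gives the same picture, and the difference from chance was not tested.

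Single H3K27me3 domains followed opposite courses. On chromosome 11, the 130 kb from 116180001 to 116310000 stood at 1.42, 2.08, 10.9 and 20.5 times IgG at P0, P5, P15 and adult, 4.52-fold (95% CI 4.18 to 4.89) up from P0 to adult relative to the median domain. On chromosome 19, the domain from 57590001 to 57640000 stood at 1.33, 1.05, 6.03 and 20.5 times IgG. On chromosome 14, the domain from 122850001 to 122890000 went the other way, from 7.05 and 7.11 at P0 and P5 to 1.998 and 2.26 at P15 and adult. On chromosome 11, the domain from 98180001 to 98220000 stood at 5.78, 12.4, 2.77 and 2.36.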
